A study of Mus musculus with 25 samples.

How the data were processed

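RNA was measured by bulk RNA sequencing in 25 lungs of female wild-type C57BL/6 mice. The sample labels give the strain as C57BL/6J, while the study's design text gives C57BL/6cmdb. Mice received house dust mite extract, a mixture of mite allergens and microbial products used to provoke allergic airway inflammation, by the intranasal route. The labels give 10 µg and 100 µg for mice killed after 2 weeks and 100 µg for mice killed after 12 weeks. Controls are called untreated in one label and saline-treated in the protocol, and they are called saline here. Each of the 5 groups holds 5 libraries, and the groups were taken from the treatment and time labels. The dosing schedule, the time of day of collection, the order of library preparation and any batch were not given in the sources used here.

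Per the labels' protocols, lung lobes were kept in an RNA-preserving solution, and total RNA of high integrity was made into libraries with the TruSeq Stranded Total RNA kit. Reads were aligned with STAR 2.5.3a to the GRCm38 build, per the submitters' processing notes. The counter, its strand setting and the annotation release were not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be shared between them. The deposited table holds whole-number counts per gene for every library, not normalized, under Ensembl gene identifiers. A kit that sequences total RNA keeps non-coding and unspliced RNA, so a gene's count can include intronic transcripts if the counter admitted them.

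The table held 55421 genes, of which 99.5% could be given a symbol from a table of gene names. Coordinates are those of the GRCm38 annotation of the same identifiers. All 25 columns were used, and 0 columns belonged to samples outside the labels. Totals ran from 25.4 M to 51.9 M counts (M, mega) in 24 libraries and came to 7.23 M in replicate 4 of the libraries labelled saline at 2 weeks. In all 300 pairs of libraries, within and across groups, counts differed by more than sampling noise in a chi-square test (lowest chi-square per degree of freedom 13.1), so none was treated as deposited more than 1 time. Error estimates across mice reflect biological and technical spread together. The labels number the mice within a group and do not say that equal numbers share a cage, day or batch.

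Genes with low counts were removed with the filterByExpr function of edgeR 4.0.16, which left 19654 genes. Library sizes were scaled by the trimmed mean of M values, and CPM values (counts scaled to a total of 1e+06 per library) below are normalized by it. The test was edgeR's quasi-likelihood F-test with all 25 libraries in 1 fit, run in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Values are means ± SD over the 5 mice of a group unless stated, and log2 fold changes carry their standard error (SE). Where all libraries of the lower group held 0 counts, the fold was computed against a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio of summed counts over summed library sizes is given with its exact conditional binomial interval at 95%. Both cover counting error only.

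Before the data were examined, 6 comparisons were fixed: 10 µg against saline, 100 µg against saline and 100 µg against 10 µg at 2 weeks, 100 µg against saline at 12 weeks, the difference between the 100 µg effects at both times, and saline at 12 weeks against saline at 2 weeks. A further comparison, 100 µg at 12 weeks against 100 µg at 2 weeks, was added after the data were seen. Genes named in the text came from a rule also fixed beforehand. It takes, per comparison, up to 5 genes with the largest rise and 5 with the largest fall among called genes with a mean of at least 1 CPM, a symbol that is not a predicted or antigen receptor segment gene, and every mouse of one group above every mouse of the other (no such separation was asked for the difference). It adds a panel of 25 allergy and remodelling genes in every comparison, and up to 4 members with the smallest p from each list described. Genes that the rule names but that are not reported here were kept in every fit and list test and left out of counts over the named genes.

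Gene lists were also fixed beforehand: 44 lists of pathways, matrix classes, immune and structural cell markers, and genes of tissue that can be taken along with lung, such as blood, heart, fat and thymus. Each list was tested with camera (limma 3.58.1), two-sided, with the correlation between members estimated from the data, and adjusted over the lists. Camera with a preset correlation of 0.01 and fry were alternatives. Camera compares a list with the other genes, while fry asks whether its members move one way on balance.

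Alternatives fixed beforehand were DESeq2 size factors and upper-quartile scaling in the same fit, no filter and a stricter filter (at least 1 CPM in 5 libraries), limma-voom, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, a 2-fold threshold, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a covariate made from clock genes (mean log2 CPM of Dbp and Per3 minus that of Arntl and Npas2), removal of clock and ribosomal RNA genes before normalization, and removal of the 2-week saline replicate 4 from comparisons that do not use it.

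The procedure was tested on simulated data drawn from the means and library sizes of these libraries, with 50 genes changed at each fold. In the comparison of 100 µg against saline at 2 weeks, over 19433 simulated genes, it recovered 54% of genes changed 1.5-fold, 86% at 2-fold and 100% at 4-fold. For 100 µg against saline at 12 weeks, over 19421 genes, it recovered 50%, 80% and 100%. For the difference between the effects, also over 19421 genes, it recovered 26%, 50% and 100%. For 100 µg against 10 µg, over 19433 genes, it recovered 54%, 80% and 100%. False calls made up 5.03%, 4.62%, 4.20% and 7.22% of calls in these comparisons, in that order. Only genes with a mean of at least 1 CPM were changed, and 1 spread per gene served all groups. Recovery of rarer genes, or under a larger spread at 12 weeks, was therefore not tested. Figures were drawn with matplotlib 3.10.9.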

Results

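Lung RNA was counted per gene in 25 mice, 5 in each of 5 groups: saline, 10 µg and 100 µg of house dust mite extract in the 2-week model, and saline and 100 µg in the 12-week model. Total counts (M, mega) ranged from 7.23 to 46.2 M in the libraries labelled saline at 2 weeks, 31.3 to 51.9 M at 10 µg, 28.9 to 35.7 M at 100 µg and 2 weeks, 29.6 to 44.2 M in those labelled saline at 12 weeks, and 32.7 to 40.7 M at 100 µg and 12 weeks. The shallowest library, replicate 4 of those labelled saline at 2 weeks, held 27.8% ribosomal RNA and 9.80% mitochondrial counts, and its median Spearman correlation with its group was 0.972, against 0.990 to 0.991 for the other 4. Mitochondrial genes held 1.99 to 3.59% of counts in those 4, 3.25 to 4.02% at 10 µg, 3.27 to 6.64% at 100 µg and 2 weeks, 4.26 to 7.16% in the libraries labelled saline at 12 weeks and 2.5 to 4.21% at 100 µg and 12 weeks. The first principal component held 49.6% of the variance and the second 13.2%. All 15 libraries of the 2-week model lay at or below -15.6 on the first, the libraries labelled saline at 12 weeks lay between 49.2 and 91.6, and those labelled 100 µg at 12 weeks between 26.7 and 87.2. The largest contrast in the data was therefore between the models, and it included the groups labelled saline. Markers of allergic inflammation were high in the libraries labelled saline at 12 weeks, which goes against that label, so groups are called by their labels throughout and every direction drawn against the 12-week saline group rests on a label in doubt. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for lists are from camera.

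**Figure D1:**
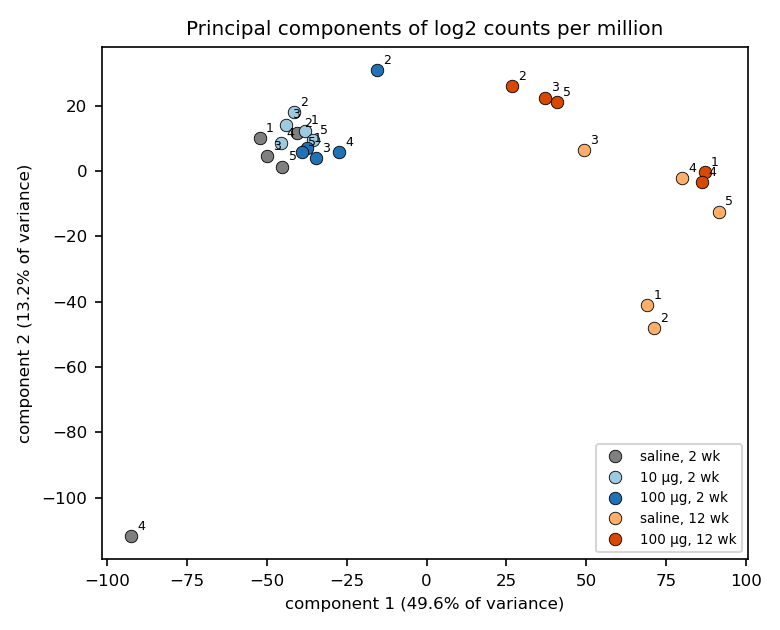
Each library's position on the first 2 principal components of log2 CPM (axes carry the percent of variance, 49.6% and 13.2%), with points coloured by labelled group and numbered by replicate. The 2-week libraries lie at or below -15.6 on the first component, the 12-week libraries at or above 26.7, and replicate 4 of the libraries labelled saline at 2 weeks sits apart at -112 on the second.

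The comparison of 10 µg against saline at 2 weeks asked what the low dose did in the short model. Dbp, a transcription factor of circadian output, rose from 19.3 ± 11.2 to 59.2 ± 22.6 CPM (SD, n = 5 each), a log2 fold change of 1.61 with an SE of 0.30 and an adjusted p of 0.0456. Dbp (ENSMUSG00000059824) lies at 45705088 to 45710203 on chromosome 7 of GRCm38. Lingo1, a membrane protein known for limiting neurite growth, rose from 0.339 ± 0.103 to 0.933 ± 0.183 CPM, and Gpsm3, a modulator of G protein signalling in leukocytes, from 5.48 ± 1.48 to 10.3 ± 1.07. The C-type lectin receptor gene Clec4a1, of myeloid cells, rose from 3.24 ± 0.295 to 5.26 ± 0.687 CPM. Gprin3, named for its part in G protein-regulated neurite growth, fell from 109 ± 13.2 to 73.7 ± 6.67 CPM, and Nbea, a membrane trafficking gene, from 99.2 ± 3.74 to 80.02 ± 2.36. Kctd14 also rose, by 0.99 log2 (SE 0.19, adjusted p = 0.0484). In all, 8 genes were called, 6 higher and 2 lower, and 2457 stood at an unadjusted p under 0.05. Mitochondrial ribosomal RNA took 0.935 to 1.59% of counts at 10 µg, against 0.172 to 1.02% in the libraries labelled saline without replicate 4, which held 5.89%.

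None of the 25 panel genes was called at 10 µg (edgeR, smallest adjusted p = 0.464, for the IL-33 receptor gene Il1rl1 at -0.38), with limma-voom calling 0 genes of any kind and DESeq2 202. Their log2 fold changes ran from -0.91 for Il13 to 1.01 for Clca1, a goblet cell secreted protein. Retnla, made by alternatively activated macrophages, stood at -0.14 (adjusted p = 0.874), the airway mucin gene Muc5ac at 0.26 (adjusted p = 0.884) and Col1a1 at 0.17 (adjusted p = 0.782). Among 13 circadian clock genes tested, 1 was called over all genes, and 5 rose and 4 fell when adjusted over the list alone, with an adjusted p of 0.998 with an estimated correlation. Those near the threshold included Npas2 at -0.87 (adjusted p = 0.103), Per3 at 0.67 (adjusted p = 0.105) and Arntl at -0.70 (adjusted p = 0.141). Of 10 B cell markers 0 were called, and 1 rose adjusted over the list alone, Cd79a of the B cell receptor at 0.72. That list had an adjusted p of 0.00746 with the preset correlation and an adjusted p of 0.998 with an estimated correlation. No list of the 44 moved by camera with an estimated correlation, fry moved 0, and 1 had an unadjusted p under 0.05. The chemokine gene Ccl5 stood at 0.93 (adjusted p = 0.0763). The decoy receptor gene Il13ra2 held 1 count over the 10 µg libraries and 16 over those labelled saline, a ratio of saline to 10 µg of 21.5 (95% counting interval 3.35 to 904, adjusted p = 0.0854). The count of 8 fell to 0 without replicate 1 or 3 of the libraries labelled saline or replicate 1, 2, 3 or 5 at 10 µg, was 3 and 4 without saline replicates 2 and 4, 49 without saline replicate 5 and 57 without replicate 4 at 10 µg. With the 2 compared groups alone it was 0, and with DESeq2 size factors 2 genes rose and 0 fell.

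At 100 µg and 2 weeks against the same saline libraries, clock genes changed in 11 of 13 tested. Dbp rose from 19.3 ± 11.2 to 108 ± 15.0 CPM (n = 5 each), a log2 fold change of 2.47 (SE 0.31, adjusted p = 0.000214). Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, GRCm38), fell from 64.1 ± 11.9 to 22.0 ± 5.16 CPM, a change of -1.54 (SE 0.20, adjusted p = 0.000214). The period gene Per3 rose by 1.33 (SE 0.17), while Clock, the partner of BMAL1, changed by -0.59 (SE 0.10) and its paralog Npas2 by -1.21 (SE 0.22). Of 13 clock genes tested 7 rose and 4 fell (8 and 4 adjusted over the list alone), with an adjusted p of 0.66 with an estimated correlation. That test looks for 1 direction and is weak for a list that moves both ways. For changes in either direction fry gave a p of 1.91e-05, not adjusted over the lists. Rps16, a ribosomal protein gene, rose from 21.5 ± 13.9 to 97.6 ± 12.3 CPM, and the ribosomal RNA gene n-R5-8s1 by 2.93 (SE 0.80, adjusted p = 0.0264), where the share of ribosomal RNA itself varied between libraries. Without saline replicate 5 the saline libraries held 2 counts of n-R5-8s1, and the ratio was 56.9 (95% counting interval 15.5 to 473). Lingo1 rose by 1.94 (SE 0.26) and Epop by 1.67 (SE 0.31). Adrenomedullin (Adm), a vasodilator peptide, fell from 15.7 ± 3.42 to 7.12 ± 0.549 CPM. Spon2, a secreted matrix protein, changed by -1.23 (SE 0.22, adjusted p = 0.00224), the zinc finger gene Zfp970 by -1.25 (SE 0.25) and the vasopressin receptor gene Avpr1a by -1.16 (SE 0.34, adjusted p = 0.038). Mitochondrial ribosomal RNA took 1.59 to 3.19% of counts at 100 µg, above the 0.172 to 1.02% of every library labelled saline except replicate 4, at 5.89%.

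Some collagen, B cell and chemokine genes also changed at 100 µg and 2 weeks, where the mitochondrial share of counts (3.27 to 6.64%) lay mostly above that of the libraries labelled saline without replicate 4 (1.99 to 3.59%). Col1a1, the major chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, GRCm38), rose from 103 ± 11.2 to 180 ± 61.3 CPM (n = 5 each), a log2 fold change of 0.81 (SE 0.22, adjusted p = 0.0245), and was the only panel gene called. Col6a1, a chain of the microfibril-forming type VI collagen, rose from 223 ± 15.5 to 333 ± 54.1 CPM and Col6a2 by 0.58 (SE 0.14), while P4ha1, a prolyl hydroxylase for collagen folding, changed by -0.47 (SE 0.11). Among 21 fibrillar collagen and cross-linking genes 7 rose and 1 fell (10 and 2 adjusted over the list alone), with an adjusted p of 0.85 with an estimated correlation. The list's score, as mean log2 CPM relative to the libraries labelled saline, was highest in replicate 2 at 100 µg, at 0.574. It was 0.061 to 0.235 in the others at 100 µg, 0.066 to 0.139 at 10 µg and -0.039 to 0.043 in the libraries labelled saline. Of 10 B cell markers 4 rose (5 adjusted over the list alone), with an adjusted p of 0.766 with an estimated correlation. Among them were Cd79a, from 12.5 ± 2.53 to 25.8 ± 7.33 CPM, Fcrla at 0.66 (SE 0.18) and the low-affinity IgE receptor gene Fcer2a at 0.67 (SE 0.20). The T cell (15 tested), natural killer cell (8) and plasma cell (16) lists gave 0 calls, and 1 of 11 lymphoid aggregate genes rose. The counts were the same adjusted over the list alone. With an estimated correlation these lists had an adjusted p of 0.85, 0.985, 0.985 and 0.766 in that order. Among 25 chemokines 4 rose, both over all genes and adjusted over the list alone (adjusted p = 0.985 with an estimated correlation), among them Ccl22 at 0.75 (SE 0.20) and Cx3cl1 at 0.62 (SE 0.15). Hspa5, an endoplasmic reticulum chaperone, fell from 456 to 327 CPM, and Hsp90b1 changed by -0.45 (SE 0.13). They were the 2 called of 10 unfolded protein response genes (3 fell adjusted over the list alone), with an adjusted p of 0.689 with an estimated correlation. Gata3, the regulator of type 2 helper cells, rose by 0.52 (SE 0.14, adjusted p = 0.0245) and was the only one called of 16 type 2 cytokine and receptor genes. Alternatively activated macrophage genes (14 tested) and mucus genes (13 tested) gave 0 calls each, with both lists at an adjusted p of 0.985 with an estimated correlation.

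At 100 µg and 2 weeks 24 of the 25 panel genes were not called. Retnla was at 43.8 ± 11.4 CPM in the libraries labelled saline and at 42.6 CPM with 100 µg (log2 fold change -0.02, adjusted p = 0.979). Muc5ac stood at 1.18 (adjusted p = 0.191) and the macrophage elastase gene Mmp12 at -0.15 (adjusted p = 0.911). Outside the panel, the antibody gene Ighg1 stood at 1.9 (adjusted p = 0.398) and the regulatory T cell gene Foxp3 at 0.98 (adjusted p = 0.0638). The alarmin gene Il33 stood at -0.44 (adjusted p = 0.0741), Tgfb1 at 0.54 (adjusted p = 0.0572) and the matrix phosphoprotein gene Spp1 at -1.19 (adjusted p = 0.0735). For Spp1 every mouse at 100 µg, at 52.2 to 65.5 CPM, lay below every mouse labelled saline, at 67.4 to 191. Il17a and Ighe held at most 1 count in either group, and of the other panel genes values ran from -0.87 for Epx to 0.82 for Clca1. In this comparison 1597 genes were called, 809 higher and 788 lower, with 4791 at an unadjusted p under 0.05 and 110 changed at least 2-fold. No list moved by camera with an estimated correlation, 3 lists stood at an unadjusted p under 0.05, 6 moved with the preset correlation and 3 by fry. The count was 611, 941, 737 and 1033 without replicates 2, 3, 4 and 5 at 100 µg, and 944 and 789 without saline replicates 2 and 3. It was 244 in a fit of the 2 groups alone and 0 with the clock covariate, which was added after the data were seen and is built from genes that changed here.

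Comparing 100 µg with 10 µg at 2 weeks asked whether the dose mattered. No gene was called by edgeR, with 1666 at an unadjusted p under 0.05, 0 by limma-voom and 1 by DESeq2. The list of 10 unfolded protein response genes fell at the higher dose, with a median log2 fold change of -0.20 (adjusted p = 0.0194 with an estimated correlation), although 0 members passed over all genes and 2 fell adjusted over the list alone. Hspa5 went from 436 ± 32.6 to 327 CPM (-0.42, SE 0.11, adjusted p = 0.434, n = 5 each), and Ddit3, a stress-induced transcription factor, from 12.9 ± 1.63 to 9.78 ± 0.937 (-0.40, adjusted p = 0.464). Atf4 stood at -0.19 (adjusted p = 0.548) and Hsp90b1 at -0.28 (adjusted p = 0.561). Without replicate 4 at 10 µg or replicate 3 at 100 µg, 0 lists moved. Clock genes lay in the direction seen against saline, with Arntl at -0.84, Per3 at 0.66 (adjusted p = 0.434 for both) and Dbp at 0.87 (adjusted p = 0.466), and 6 rose and 2 fell of 13 adjusted over the list alone (adjusted p = 0.596 with an estimated correlation). Col1a1 stood at 0.64 (adjusted p = 0.473). Apart from Il17a and Ighe, which held at most 1 count in either group, the panel ran from -0.64 for S100a8 to 1.18 for Il5.

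The fold changes of both doses against saline had a Pearson r of 0.713 across 19654 genes, which are not independent replicates, and 78.5% had the same sign. Unchanged groups and shared saline libraries were also simulated, all from the means of the libraries labelled saline. They gave a mean r of 0.541 (highest of 20, 0.563) and 67.7% with the same sign. The covariance was 0.0974, against 0.0423 in the simulations, an excess of 0.0551. The simulated saline libraries had 1 spread per gene and independent genes, so the deviations of the poor saline library are not in them. The excess may therefore hold noise of the shared controls. With the saline libraries split between the doses, r had a median of 0.222 over 20 splits, from 0.163 to 0.313, and the covariance a median of 0.0453. Each dose then had only a part of the saline libraries as controls, and the noisier fold changes lower r too. All 6 genes that rose at 10 µg and both that fell were called likewise at 100 µg, where independent lists would share 0.247 and 0.0802. The unchanged groups simulated with shared saline libraries had 0 calls in common in each of 20 draws. In these the group standing for 10 µg had at most 2 calls to share. With the saline libraries split between the doses, 10 µg itself gave a median of 0 calls over 20 splits (0 to 82) and both doses together a median of 0 (0 to 14). The splits therefore do not settle how much of the overlap comes from the shared controls.

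The comparison of the groups labelled saline, 12 weeks against 2 weeks, was planned as a check of the controls and gave the largest changes. Ighe, the constant region of IgE (ENSMUSG00000087642, chromosome 12, 113269260 to 113273248, GRCm38), had 0 counts in all 5 libraries labelled saline at 2 weeks and 25.02 ± 31.3 CPM in those labelled saline at 12 weeks, at least 1247-fold higher against a floor of 3 counts over the group. Replicate 2 held 79.8 CPM of it, and without that library the mean was 11.3 ± 7.67 CPM, at least 565-fold higher. Ighg1 rose from 0.358 CPM to 2187 ± 1601 (12.73 log2, and 13.41 without replicate 2 of the libraries labelled saline at 2 weeks), and Igha by 6.21 log2 (SE 0.50, adjusted p = 2.13e-09). Among 16 plasma cell and immunoglobulin genes 13 rose, also adjusted over the list alone (adjusted p = 0.126 with an estimated correlation). Reads of near-identical constant regions may be shared, so values of single isotypes are uncertain. Mucus and goblet cell genes rose in 13 of 13 tested, over all genes and adjusted over the list alone, with an adjusted p of 0.126 with an estimated correlation. Muc5ac (ENSMUSG00000037974, chromosome 7, 141788972 to 141819231, GRCm38) rose from 1.58 ± 1.56 to 96.3 ± 40.7 CPM, a log2 fold change of 6.51 (SE 0.55, adjusted p = 3.35e-09). Clca1 rose by 6.97 (SE 1.36, and 7.64 without replicate 4 of the libraries labelled saline at 2 weeks), the anion exchanger gene Slc26a4 by 5.29, and Itln1, a lectin of goblet cells, from 0 counts to 6.73 ± 3.66 CPM, at least 335-fold.

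Macrophage, chemokine and lymphocyte genes rose with them in the libraries labelled saline at 12 weeks. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, GRCm38) rose from 43.8 ± 11.4 to 997 ± 288 CPM, by 4.53 (SE 0.32, adjusted p = 4.83e-10). Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, GRCm38) rose from 9.22 ± 2.92 to 1274 ± 640 CPM, by 7.19 (SE 0.70). Arg1, an arginine-degrading enzyme, rose by 5.2, Pdcd1lg2, the PD-1 ligand PD-L2, by 4.58, and the chitinase-like gene Chil4, close to Chil3 in sequence and so uncertain, by 10.94. Of 14 alternatively activated macrophage genes 13 rose (adjusted p = 0.073 with an estimated correlation). Rnase2a, of the eosinophil ribonuclease family, rose by 11.38 (SE 0.98), 6 of 8 eosinophil markers rose (adjusted p = 0.25 with an estimated correlation), and Epx, eosinophil peroxidase, stood at 0.88 (adjusted p = 0.303). Among 25 chemokines 22 rose and 1 fell (adjusted p = 0.073 with an estimated correlation), with Ccl8 at 6.17, the eotaxin genes Ccl11 at 2.80 and Ccl24 at 4.09. Il4 rose by 3.41, Il13 by 3.96 and Il33 by 0.93, while Il5 stood at 1.07 (adjusted p = 0.0879). Il17a rose from 1 count to 233 over the group, a ratio of 204 (95% counting interval 36.3 to 8092). Without replicate 2 of the libraries labelled saline at 2 weeks, which held that count, it was at least 49.1-fold higher. Without their replicate 1 Il13 had 1 count left at 2 weeks, a ratio of 101 (95% counting interval 17.8 to 4014). Type 2 genes rose in 11 and fell in 2 of 16, type 17 genes rose in 9 of 10, T cell markers in 13 of 15 (Cd4 by 1.92, Foxp3 by 3.23), B cell markers in 8 of 10 (Cd79a by 1.55), dendritic cell markers in 9 of 12 (Fscn1 by 2.32), monocyte and interstitial macrophage markers in 10 of 11 (C1qb by 2.58), lymphoid aggregate genes in 8 of 11 (Cxcl13 by 2.16) and proliferation genes in 12 of 12 (Mki67 by 2.10). With an estimated correlation none of these 8 lists passed, at an adjusted p of 0.149, 0.073, 0.0748, 0.284, 0.073, 0.073, 0.0748 and 0.149 in that order. The counts in these lists were the same adjusted over the list alone.

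In the same comparison the matrix lists held more rises than falls, and most club, ciliated and alveolar type 1 cell markers fell. Col1a1 rose from 103 ± 11.2 to 578 ± 118 CPM (2.49, SE 0.23, adjusted p = 7.66e-09), Col3a1 by 1.83, the adhesive glycoprotein genes Fn1 by 2.07 and Tnc by 2.60, the metalloprotease inhibitor gene Timp1 by 2.88 and Tgfb1 by 1.82. Fibrillar collagen genes rose in 15 and fell in 3 of 21, matricellular genes rose in 11 and fell in 3 of 20, basement membrane genes rose in 11 of 21, and matrix proteases rose in 13 and fell in 2 of 21. With an estimated correlation none passed, at an adjusted p of 0.163, 0.149, 0.527 and 0.176 in that order. Postn, a matricellular gene of type 2 inflammation, fell by 0.57, and the neutrophil gene S100a8 by 1.44, whereas Spp1 (0.87, adjusted p = 0.0732) and the smooth muscle actin gene Acta2 (-0.16, adjusted p = 0.378) were not called. Complement C3 rose by 1.80, Lcn2 by 3.68 and Saa3 by 5.26, in a complement and acute phase list with 8 rises and 2 falls among 13 (adjusted p = 0.126 with an estimated correlation). The club cell secretory protein gene Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958, GRCm38) fell from 27703 ± 10938 to 8786 ± 2349 CPM, a change of -1.66 (SE 0.26), Cyp2f2 changed by -1.64 and Scgb3a2 by -1.96, with 6 of 8 club cell markers lower (adjusted p = 0.149 with an estimated correlation). Alveolar type 1 markers fell in 5 of 8 (Cav1 by 1.30), endothelial markers in 7 of 12 (8 adjusted over the list alone, Kdr at -0.79) with 2 higher, and ciliated cell markers in 6 of 10 (7 adjusted over the list alone). Their adjusted p with an estimated correlation were 0.137, 0.21 and 0.596. The largest falls by the fixed rule were in Asgr1 (-4.08), Cst8 (-3.79), Pon1 (-3.79, from 62.6 to 4.55 CPM), Fabp1 (-3.47, and -4.13 without replicate 3 of the libraries labelled saline at 12 weeks) and Acaa1b (-3.07), of which Pon1, Fabp1 and Asgr1 are known from liver.

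Together 10634 genes were called, 5609 higher and 5025 lower in the libraries labelled saline at 12 weeks, 3213 of them at least 2-fold, with 11564 at an unadjusted p under 0.05. Of the 25 panel genes 19 rose, 2 fell and 4 were not called. No list passed camera with an estimated correlation, with 12 lists at an unadjusted p under 0.05, 22 moved with the preset correlation and 28 by fry. The smallest adjusted p with an estimated correlation was 0.073. Of tissue taken along with lung, red blood cell genes fell in 4 of 6, adipose genes in 2 of 6 (4 adjusted over the list alone), cardiac muscle genes in 0 of 9, and thymus genes rose in 1 of 4, with adjusted p of 0.617, 0.789, 0.789 and 0.984 with an estimated correlation. Clock genes rose in 8 and fell in 3 of 13 (9 and 3 adjusted over the list alone, adjusted p = 0.789 with an estimated correlation), with Dbp at 2.40, Arntl at -2.12 and Clock at -1.08. With the clock covariate, added after the data were seen, 4270 genes were called, 4011 of them shared. Mitochondrial ribosomal RNA took 2.93 to 4.39% of counts in the libraries labelled saline at 12 weeks, and at 2 weeks 0.172 to 1.02% without replicate 4.

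**Figure D2:**
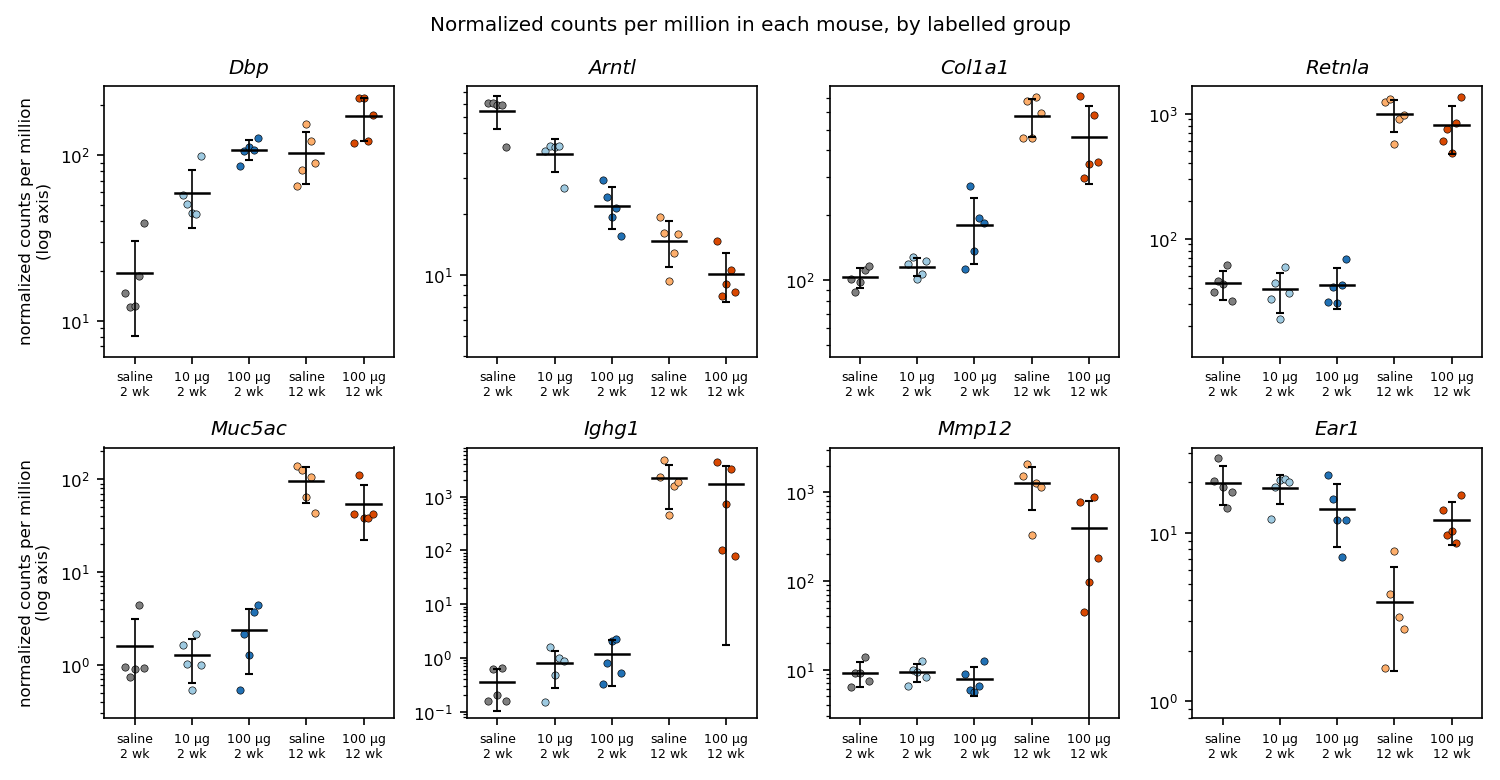
CPM (log axis) of 8 genes in each mouse of the 5 labelled groups, with points for mice, a line for the mean and a bar for the SD, its lower end shortened where the SD exceeds the mean. Retnla, Muc5ac, Ighg1 and Mmp12 are high in both 12-week groups, with Retnla at a mean of 997 CPM in the libraries labelled saline and 806 CPM in those labelled 100 µg, whereas Dbp and Arntl move apart across the 2-week groups.

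The libraries labelled 100 µg at 12 weeks were set against those labelled 100 µg at 2 weeks, a comparison added after the data were seen. Retnla rose from 42.6 to 806 ± 335 CPM (n = 5 each), by 4.24 (SE 0.31, adjusted p = 2.21e-09), and Muc5ac from 2.40 to 54.6 ± 32.4 CPM, by 4.52 (SE 0.47). Mmp12 rose from 7.91 to 396 ± 400 CPM, Col1a1 from 180 to 460 ± 182, and Ighg1 from 1.2 to 1706 ± 1978.5 (10.48 log2, and 9.72 without replicate 1 at 12 weeks). Ighe rose from 1 count over the libraries at 2 weeks to 21.5 ± 25.3 CPM, a ratio of 3284 (95% counting interval 589 to 129730), or 2075 (372 to 81984) without replicate 1 at 12 weeks. Without replicate 3 at 2 weeks, which held that count, it was at least 971-fold higher. Neuropeptide Y (Npy), absent from all 5 libraries at 2 weeks, stood at 3.99 ± 5.57 CPM, at least 220-fold higher and at least 98.7-fold without replicate 1, which held 12.8 CPM, and Il17a, also at 0 counts, at 0.936 CPM, at least 51.7-fold higher. Chil4 rose by 7.73, Rnase2a by 10.70, Igha by 6.83, Arg1 by 3.69, Clca1 by 5.74, Slc26a4 by 4.69, Il13 by 3.97, Il33 by 1.13 and Col3a1 by 1.48. Itln1 rose from 3 counts, a ratio of 215 (95% counting interval 73.1 to 1043). Without replicate 5 at 2 weeks Chil4 stood at 10.59 and Clca1 at 9.05. With 1 count left for each, Itln1 then had a ratio of 525 (94.0 to 20769) and Il13 of 70.0 (12.3 to 2793). Without replicate 4 at 2 weeks Rnase2a had 2 counts left, a ratio of 3568.5 (988 to 29470). Without replicate 4 at 12 weeks Arg1 stood at 2.96. Club cell markers fell in 7 of 8, with Scgb1a1 at -1.48 and Cyp2f2 at -1.51 (list adjusted p = 0.149 with an estimated correlation). The largest falls by the fixed rule were in the squamous gene Sprr1a (-2.34), Pon1 (-2.25), Scgb1c1 (-2.23), the protease inhibitor gene Stfa2l1 (-2.11) and the kinase gene Mapk10 (-2.07).

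With an estimated correlation 8 lists rose in this comparison. They were alternatively activated macrophages (13 of 14 genes higher), dendritic cells (11 of 12) and complement and acute phase genes (11 of 13), each at an adjusted p of 0.0206, and monocytes and interstitial macrophages (10 of 11, adjusted p = 0.0353). The other 4 had an adjusted p of 0.0372: mucus (12 of 13), chemokines (19 of 25 with 2 lower), type 17 genes (8 of 10) and the unfolded protein response (7 of 10 with 1 lower, Hspa5 at 0.49). Adjusted over the list alone, 21 chemokines and 11 monocyte genes rose and the other counts were the same. Among the called members were C1qb at 2.22, C3 at 1.67, Saa3 at 4.19, Lcn2 at 2.62 and Retnla at 4.24. Plasma cell genes rose in 14 of 16 (15 adjusted over the list alone, adjusted p = 0.0869 with an estimated correlation), type 2 genes in 10 of 16 (adjusted p = 0.0869), and proliferation genes in 12 of 12 (Mki67 at 1.34, adjusted p = 0.195). Collagen genes rose in 14 and fell in 2 of 21 (adjusted p = 0.165), and 0 of 10 B cell markers were called (adjusted p = 0.993, 0 also adjusted over the list alone). Of the panel 19 genes rose, Postn fell by 0.29 (adjusted p = 0.0444), and Il5 (0.22), Epx (1.11), Spp1 (0.60), Acta2 (-0.02) and S100a8 (-0.65) were not called. In total 7568 genes were called, 4342 higher and 3226 lower, with 1626 at least 2-fold and 9321 at an unadjusted p under 0.05. Under upper-quartile scaling 3628 rose and 4271 fell. The mitochondrial share of counts was 2.5 to 4.21% at 12 weeks and 3.27 to 6.64% at 2 weeks. With the clock covariate 4398 were called, and 0 lists moved without replicate 2 at 100 µg and 2 weeks.

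**Figure D3:**
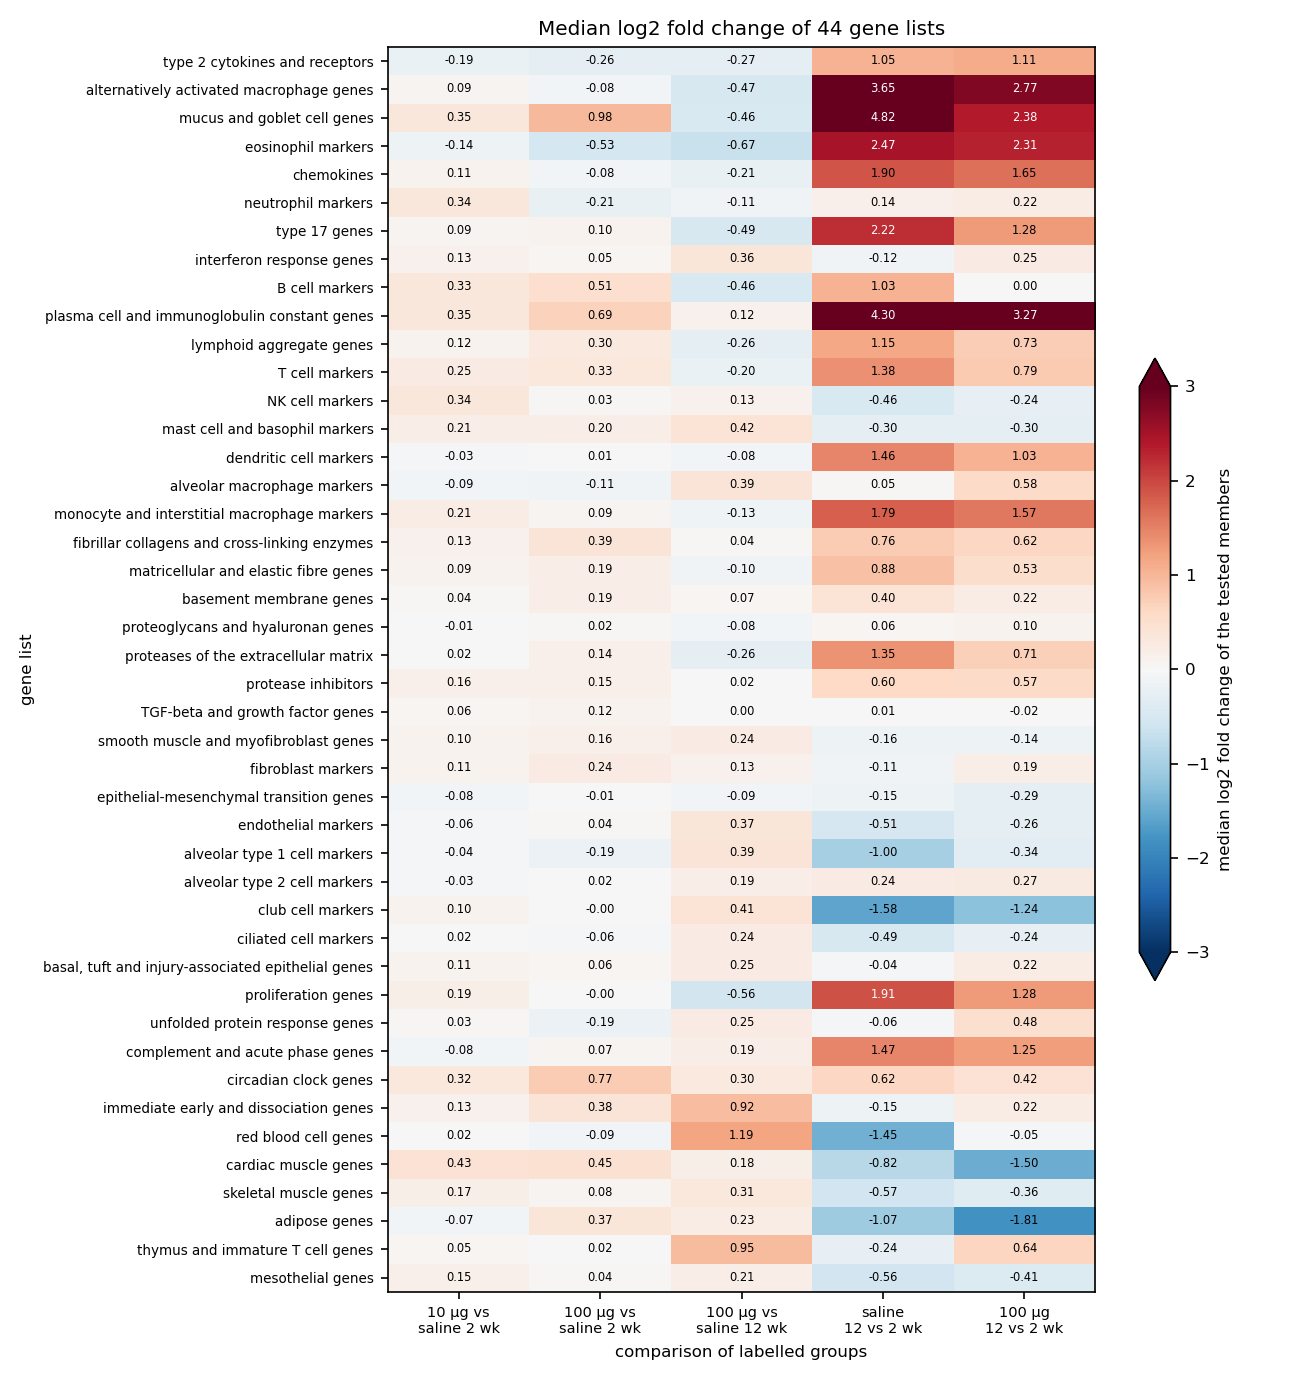
Median log2 fold change of the 44 gene lists (vertical axis) in 5 comparisons (horizontal axis), with colour from -3 to 3. Mucus, macrophage and immunoglobulin lists reach medians of 4.82, 3.65 and 4.30 between the groups labelled saline at 12 and 2 weeks, and 2.38, 2.77 and 3.27 between the 100 µg groups, the same with genes at 0 counts in a group set to their bound.

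The comparison of 100 µg against saline at 12 weeks asked what extract did in the long model, and its directions rest on the saline label. Ear1, an eosinophil-associated ribonuclease gene also used as an alveolar macrophage marker (ENSMUSG00000072601, chromosome 14, 43818765 to 43875517, GRCm38), rose from 3.92 ± 2.40 to 11.9 ± 3.38 CPM (n = 5 each), by 1.60 (SE 0.31, adjusted p = 0.0175). Its near-identical family members make the value uncertain. The scavenger receptor gene Marco rose from 5.15 to 16.6 CPM, the keratin gene Krt79 from 7.98 to 23.2, and the lipid droplet gene Cidec by 1.64 (SE 0.39). Alveolar macrophage markers rose in 4 of 10 (6 adjusted over the list alone), with an adjusted p of 0.563 with an estimated correlation. The eotaxin gene Ccl24 fell from 16.5 ± 11.7 to 3.62 ± 3.13 CPM (-2.20, SE 0.61, adjusted p = 0.033), Arg1 from 105 ± 77.2 to 30.5 ± 31.7 (-1.79, SE 0.56, adjusted p = 0.049), Spp1 from 238 ± 131 to 86.5 ± 61.9 (-1.46, SE 0.41) and Timp1 from 30.9 to 16.6 (-0.89, SE 0.28, adjusted p = 0.0494). Those 4 were the panel genes called, and 21 were not, among them Retnla (-0.31, adjusted p = 0.466), Muc5ac (-0.82, adjusted p = 0.159), Mmp12 (-1.69, adjusted p = 0.0504), Il13 (-0.63, adjusted p = 0.473), Col1a1 (-0.33, adjusted p = 0.305) and Fn1 (-0.69, adjusted p = 0.0626). Without replicate 4 at 100 µg Ccl24 stood at -2.84 and Arg1 at -2.49. The libraries labelled 100 µg lay apart from each other. On the first principal component replicates 1 and 4 were at 87.2 and 86.3, within the range of the libraries labelled saline, and replicates 2, 3 and 5 at 26.7, 37.2 and 40.9, below it. Their scores for the macrophage list, as mean log2 CPM relative to the libraries labelled saline at 2 weeks, were 3.56, 2.01, 2.22, 3.47 and 2.69 for replicates 1 to 5, against 2.77 to 3.89 in the libraries labelled saline. Arg1 stood at 49.8, 8.94, 4.34, 77.1 and 12.3 CPM in the same order.

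Some lymphocyte, vessel and immediate early genes also changed at 12 weeks. Of T cell markers 1 of 15 fell, the natural killer cell (8 tested) and plasma cell (16) lists gave 0 calls, and 2 of 10 unfolded protein response genes rose. Adjusted over the list alone the last count was 3 and the others were the same. With an estimated correlation these lists had an adjusted p of 0.635, 0.886, 0.937 and 0.563 in that order. Foxp3 fell from 5.32 ± 1.69 to 2.16 ± 0.492 CPM (-1.30, SE 0.27), and Cr2, the complement receptor of B cells and follicular dendritic cells, from 47.4 ± 19.4 to 21.2 ± 4.06 (-1.16, SE 0.25, adjusted p = 0.0189). Mucl1, a small mucin-like protein, fell from 5.90 ± 2.12 to 1.1 ± 0.839 CPM, the mitochondrial gene mt-Nd5 from 2048 to 722, and Dnm3os, a long non-coding RNA, by 1.04. The whole mitochondrial share of counts was lower too, at 2.5 to 4.21% in every library labelled 100 µg against 4.26 to 7.16% in those labelled saline, and so was mitochondrial ribosomal RNA, at 1.31 to 2.90% against 2.93 to 4.39%. Pim3, a kinase gene, rose from 21.2 to 43.9 CPM, the lipid transporter gene Mfsd2a by 1.02, Tmem160 by 1.00 and the small RNA gene Scarna2 by 0.98. The growth factor gene Csf2 fell from 17.3 to 8.11 CPM, Pdcd1lg2 from 17.6 to 6.68, and Il13ra2 by 1.28, in lists with 2 of 16 type 2 genes lower and 2 of 14 macrophage genes lower (2 and 6 adjusted over the list alone, both lists at an adjusted p of 0.563 with an estimated correlation). Endothelial markers rose in 5 of 12 (6 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation), with the tight junction gene Cldn5 from 145 ± 35.8 to 230 ± 41.1 CPM and the VEGF receptor gene Kdr at 0.36 (SE 0.10). Of other structural cells, alveolar type 1 markers rose in 1 of 8 (6 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation), with a median log2 fold change of 0.39. Adjusted over the list alone 1 of them rose without saline replicate 1 or replicate 2 at 100 µg, and 2 without saline replicate 2. Club cell markers rose in 1 of 8 (2 adjusted over the list alone) and ciliated cell markers in 1 of 10 (1 adjusted over the list alone), with all 8 and all 10 above 0 and an adjusted p of 0.635 with an estimated correlation for both. Fibroblast markers rose in 2 of 12 (4 adjusted over the list alone, adjusted p = 0.576), smooth muscle genes in 2 of 15 (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.635) and alveolar type 2 markers in 0 of 10 (0 adjusted over the list alone, adjusted p = 0.635), each with an estimated correlation. Without replicate 5 at 100 µg 0 club, ciliated, fibroblast and smooth muscle genes rose, also adjusted over the list alone, and other single libraries lowered these counts too. Immediate early genes rose in 5 of 11 (10 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation), Hspa1a from 5.28 to 18.4 CPM, Hspa1b by 1.77 and Jun by 0.59, and the near-identical Hspa1a and Hspa1b are uncertain one from the other. Proliferation genes fell in 2 of 12 (7 adjusted over the list alone), Cenpf at -0.87 and Mki67 at -0.79, B cell markers in 2 of 10 (2 adjusted over the list alone), Bank1 at -0.81 and Fcer2a at -0.64, and lymphoid aggregate genes in 2 of 11 (2 adjusted over the list alone) with Cxcl13 at -1.34. The proliferation, B cell and lymphoid aggregate lists each had an adjusted p of 0.563 with an estimated correlation. Adjusted over the list alone, 0 proliferation genes fell without saline replicate 1 or 2 or replicate 2 or 3 at 100 µg, 2 macrophage genes without saline replicate 2, and 0 type 2 genes without saline replicate 1 or 2 or replicate 3 at 100 µg. Red blood cell genes rose in 1 of 6 (5 adjusted over the list alone, adjusted p = 0.634 with an estimated correlation), Hbb-bt by 1.49, and replicate 2 at 100 µg held 0.430% haemoglobin counts. Without that library 0 rose, also adjusted over the list alone, and their median went from 1.19 to 0.40.

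In this comparison 1644 genes were called, 843 higher and 801 lower, 293 at least 2-fold, with 5838 at an unadjusted p under 0.05, and 0 lists moved with an estimated correlation (3 at an unadjusted p under 0.05, 9 with the preset correlation, 6 by fry). Under upper-quartile scaling 672 rose and 1277 fell. The count was 0 without replicate 1 or 2 of the libraries labelled saline at 12 weeks, 3500 and 987 without their replicates 3 and 5, and 3156, 31, 0 and 4 without replicates 1, 2, 3 and 5 at 100 µg. With these 2 groups alone it was 0, with the clock covariate 2, with limma-voom 3072, with DESeq2 2931 and without replicate 4 of the libraries labelled saline at 2 weeks 2843. Of 44 genes examined one by one and called here, 0 stayed called under every alternative.

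The difference between the 100 µg effects, 12 weeks minus 2 weeks, tested whether extract acted differently in the models. Of genes of the fixed rule, Fabp1 had a difference of 2.36 (SE 0.61, adjusted p = 0.0202), Fgg 2.26, Asgr1 2.23, Cst8 2.18 and Ear1 2.13 (SE 0.43, adjusted p = 0.00654), so these were relatively higher at 12 weeks. Without replicate 3 of the libraries labelled saline at 12 weeks Fabp1 stood at 2.98. Without replicate 3 at 100 µg and 12 weeks Fgg stood at 1.52 (adjusted p = 0.128), and without replicate 2 Asgr1 stood at 1.49 (adjusted p = 0.134) and Cst8 at 1.58 (adjusted p = 0.0493). On the other side stood n-R5-8s1 at -3.39, the scaffold gene Ksr2 at -3.02, Mucl1 at -2.91, Foxp3 at -2.28 (SE 0.42, adjusted p = 0.00539) and Dnase1l3, a secreted nuclease of dendritic cells and macrophages, at -2.14. Without replicate 5 of the libraries labelled saline at 2 weeks n-R5-8s1 had 2 counts left in that group, and its ratio at 2 weeks was 56.9 (95% counting interval 15.5 to 473). Without replicate 5 at 100 µg and 2 weeks Mucl1 stood at -2.11 (adjusted p = 0.101). Of the panel 3 genes were called, Col1a1 at -1.14 (SE 0.30, adjusted p = 0.0237), Timp1 at -1.49 (SE 0.42, adjusted p = 0.029) and Tgfb1 at -0.85 (SE 0.25, adjusted p = 0.034), and 22 were not. Apart from Il17a and Ighe, with at most 1 count in either 2-week group, those ran from Ccl24 at -2.02 to S100a8 at 0.79. B cell markers were lower in 6 of 10 (9 adjusted over the list alone, adjusted p = 0.385 with an estimated correlation), with Fcer2a at -1.31, Bank1 at -1.26, Fcrla at -1.11 and Cd79a at -1.1. Krt79 at 1.98 and Ear1 were among 3 higher of 10 alveolar macrophage markers (5 adjusted over the list alone, adjusted p = 0.385). Unfolded protein response genes were higher in 2 of 10 (3 adjusted over the list alone, adjusted p = 0.195), with Hspa5 at 0.74 (SE 0.16) and Ddit3 at 0.71. Clock genes were lower in 4 and higher in 2 of 13 (5 and 3 adjusted over the list alone, adjusted p = 0.792), with Dbp at -1.73, Per3 at -0.98 and Arntl at 1.00. Cav1 at 0.69 was among 3 higher of 8 alveolar type 1 markers (4 adjusted over the list alone, adjusted p = 0.728), Cldn5 stood at 0.87, P4ha1 at 0.84, Itga8 at 0.65 and Zfp970 at 1.87.

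For the difference 1624 genes were called, 932 higher and 692 lower, 353 at least 2-fold and 5146 at an unadjusted p under 0.05, and 0 lists moved with an estimated correlation (4 at an unadjusted p under 0.05, 10 with the preset correlation, 6 by fry). Under upper-quartile scaling 703 were higher and 872 lower. The count was 951 and 1035 without replicates 2 and 3 of the libraries labelled saline at 2 weeks, 1067 and 828 without replicates 3 and 4 at 100 µg and 2 weeks, 935 without replicate 1 of those labelled saline at 12 weeks, and 2602, 921, 785 and 777 without replicates 1, 2, 3 and 5 at 100 µg and 12 weeks. In a fit of these groups alone it was 978, and with DESeq2 2459. Across 19654 genes, which are not independent, the 100 µg effects at both times had an r of 0.0331 with 51.8% of the same sign. Both effects were higher for 24 genes and lower for 15, where independent lists would share 34.7 and 32.1, and 28 genes rose then fell and 32 fell then rose, against 33.0 and 33.8.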

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

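The counts of other splits of the samples were planned, while the tests of explanations below were chosen after the patterns they bear on had been seen. Their values had been seen too, except the counts with both replicate 4 of the libraries labelled saline at 2 weeks and a 12-week library left out. Within groups of 5, a library was singled out where its gap to the nearest of the others took a larger part of the group's range than the critical value of Dixon's test at the 0.05 level. Of 580 groups tested, over 110 genes and 6 library measures, 51 held such a gap, where chance gives about 1 in 20. At 2 weeks the gaps of Il17a, Ighe, Itln1, Npy and Il13ra2 below had every other library of the group at 0. There any read gives such a gap, so that rate does not hold for them.

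Replicate 4 of the libraries labelled saline at 2 weeks stood apart most often. It held 27.83% ribosomal RNA (others 0.0101 to 0.103%), 9.796% mitochondrial counts (others 1.99 to 3.59%) and a median Spearman correlation of 0.9721. Its CPM was high for Ccl11 (5.466), Muc5ac (4.373), Avpr1a (10.71), mt-Nd5 (7330) and Hsp90b1 (1130). It was low for Pim3 (8.09), Mfsd2a (1.312), Cst8 (3.717), C1qb (13.34) and C1qa (14.65), and Il5, Ksr2 and Saa3 were at 0. In the same group, replicate 5 was low for Arntl (42.89), Adm (9.849) and Hspa5 (382.9) and high for Per3 (30.61), replicate 2 was high for Il17a (0.02195) and Fgg (1.603), and replicate 3 was low for C3 (608.2).

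At 10 µg, replicate 4 was high for Clca1 (118.5 CPM), Hspa5 (493.8), Itln1 (0.0625) and Il13ra2 (0.03125), replicate 5 was low for Arntl (26.75) and high for Il17a (0.0258) and Mucl1 (0.4385), replicate 1 was low for Ear1 (12.16) and replicate 2 high for Npy (0.01906). At 100 µg and 2 weeks, replicate 1 held 0.1434% ribosomal RNA and 795.8 CPM of Hsp90b1, replicate 2 had 45.67 CPM of Pim3 and replicate 3 had 0.03325 CPM of Ighe, all above the other 4. Among the libraries labelled saline at 12 weeks, replicate 2 had 44.2 M counts and was low for Il17a (0.6411), Lingo1 (0.8471) and Adm (2.541). Replicate 3 was high for Kctd14 (5.886) and Fabp1 (2.795), replicate 4 held 0.09253% ribosomal RNA and replicate 5 was low for Mapk10 (0.471). At 100 µg and 12 weeks, replicate 1 held 0.02307% ribosomal RNA and was low for Hspa1a (3.755), Hspa1b (4.225) and Ddit3 (10.05), replicate 2 held 0.4304% haemoglobin counts and 112.5 CPM of Muc5ac, and replicate 4 was low for Epop (2.957).

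For 39 of the 110 genes examined the 100 µg effect differed between the models by the test of the difference itself (edgeR, adjusted p under 0.05). Over all genes tested 8.26% did. Some of the 39 were named because they were called in this comparison, so the 2 shares cannot be compared. Of the 39, 16 stayed called under every alternative. The splits below cannot decide on chance for this comparison, so it was not excluded. Lower at 12 weeks than at 2 weeks, as log2 differences, were n-R5-8s1 (-3.39), Ksr2 (-3.02), Mucl1 (-2.91), Foxp3 (-2.28), Dnase1l3 (-2.14), Rps16 (-1.96), Dbp (-1.73), Timp1 (-1.49), Kctd14 (-1.48), Sprr1a (-1.47), Fcer2a (-1.31), Bank1 (-1.26), Cr2 (-1.21), Ccl22 (-1.16), Col1a1 (-1.14), Lingo1 (-1.12), Fcrla (-1.11), Clec4a1 (-1.1), Cd79a (-1.1), Per3 (-0.98), Gpsm3 (-0.97) and Tgfb1 (-0.85). Higher were Fabp1 (2.36), Fgg (2.26), Asgr1 (2.23), Cst8 (2.18), Ear1 (2.13), Krt79 (1.98), Zfp970 (1.87), Pon1 (1.53), Adm (1.33), Spon2 (1.09), Arntl (1.00), Cldn5 (0.87), P4ha1 (0.84), Hspa5 (0.74), Ddit3 (0.71), Cav1 (0.69) and Itga8 (0.65).

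Alternatively activated macrophage, mucus and immunoglobulin genes, the 43 tested members of 3 lists whatever their change, had a mean score of 4.08 log2 in the libraries labelled saline at 12 weeks relative to those labelled saline at 2 weeks (39 rose), against 3.60 in those labelled 100 µg at 12 weeks and 0.309 at 100 µg and 2 weeks. Reads carried over from the 100 µg libraries of the same model at under 50% of their level there would keep the score lower in the libraries labelled saline. It was 0.478 higher (SE 0.307), which argues against such reads as the whole cause. The bound set for this was a score at least 1 lower. It is approximate, since a gene's own reads add to carried ones and not every gene rose. An exchange of labels between the groups labelled saline at 12 weeks and 100 µg at 2 weeks needs the latter to sit near the saline level. Its genes had a median log2 fold change of 0.528 (SD 0.963; 0.37 with the 3 genes at 0 counts in a group set to their bound) with 0 called, but a weak response to extract would look alike, so the pair cannot be told apart. A difference that comes with the longer model, such as age, remains open and untested, since 90.7% of the genes (39) rose between the 100 µg groups too, where extract could raise them as well, and no label separates it from time.

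Clock genes differed between the 2-week groups, with a mean clock score of -0.398 in the libraries labelled saline, 1.55 at 10 µg and 2.95 at 100 µg. At 12 weeks the mean score was 3.63 in the libraries labelled saline and 4.80 at 100 µg. A difference in the time of day of collection is possible and was not tested directly. Clock genes that rose and clock genes that fell also deviated oppositely between mice of the same group (Pearson r = -0.826, permutation p = 7e-05, Spearman rho = -0.761, permutation p = 6e-05, 25 libraries, 100000 resamples, 1 relation computed). Any shift of the clock between mice would give such a relation, so it does not favour collection time over the extract. Without the 2 libraries farthest from the median, r was -0.787. An effect of the extract's dose cannot be told apart from one of collection time, since the collection times were not given. At 100 µg against saline at 12 weeks, which shares no library with the 2-week groups, 1 of the 11 clock genes called at 100 µg was called likewise and 0 oppositely (8 had the same sign).

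The count of genes changed at 100 µg and 12 weeks ran from 0 to 3500 with the libraries in the fit. Replicate 4 of those labelled saline at 2 weeks is argued against as the whole cause, since without it in any fit the counts still ran from 27 to 4583 as each 12-week library was left out. It had an influence, with 2843 genes in place of 1644 called without it alone. A larger spread between 12-week mice may contribute, as the biological coefficient of variation was 0.220 over the 12-week libraries and 0.165 over the 2-week ones, a ratio of 1.33. A biological difference between these mice was not tested.

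Each comparison was set against 100 splits of its libraries, the real one included. At 10 µg, 2 of 100 gave as many genes as the real 8 (highest other 38), and at 12 weeks 4 did (1644, highest other 3759). Both lie under the limit of 5 of 100 set beforehand. Other splits called more genes than the real one, with no adjustment over comparisons, so chance is not excluded there. At 100 µg and 2 weeks only the real split gave as many (1 of 100, 1597, highest other 300). The same held between the groups labelled saline, 12 against 2 weeks (1 of 100, 10634, highest other 5406), and between the 100 µg groups (1 of 100, 7568, highest other 4778). The splits drawn argue against chance in these, without adjustment over comparisons. For 100 against 10 µg the real count was 0 (highest other 0), which any split matches, so the splits decide nothing there. For the difference 5 of 100 gave as many as 1624 (highest other 5231), which is at the limit. Its splits shuffled the time labels within each treatment, so uneven ones carried the large change between the models into the contrast. They cannot decide on chance, which is not excluded for the difference. Splits that call several times the real count, as at 10 µg and at 12 weeks, point to a structure of the samples.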

How the results depend on the processing

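The fits with the clock covariate, without clock and ribosomal RNA genes, without replicate 4 of the libraries labelled saline at 2 weeks where it was not compared, and of 100 µg at 12 against 2 weeks were chosen after the data were seen. Of 292 gene results called, 141 stayed called under every alternative and 151 were lost or reversed under at least 1. By comparison, 0 of 7 were kept at 10 µg, 0 of 31 at 100 µg and 2 weeks, 0 of 44 at 12 weeks, 16 of 39 for the difference, 72 of 93 between the groups labelled saline and 53 of 78 between the 100 µg groups. The clock covariate, which is itself built from genes that differ between groups, removed or reversed all 31 at 100 µg and 2 weeks and all 44 at 12 weeks. At 2 weeks its score ran from -0.985 to 1.14 in the libraries labelled saline and from 2.60 to 3.44 at 100 µg, without overlap. Of the 31, each other alternative lost at most 9, the number with the compared groups alone. At 12 weeks leaving out replicate 1 of the libraries labelled saline also lost all 44. The cause of the changes below was not tested.

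At 10 µg the count of 8 became 2 at a 2-fold threshold, 2 with DESeq2 size factors, 3 with upper-quartile scaling, 2 without a filter, 0 with the clock covariate, 3 without clock and ribosomal RNA genes, 0 with limma-voom, 202 with DESeq2 (8 shared) and 0 with the compared groups alone. At 100 µg and 2 weeks 1597 became 110 at 2-fold, 723 without a filter, 0 with the clock covariate and 244 with the compared groups alone. For dose, 0 became 1 with DESeq2. At 12 weeks 1644 became 293 at 2-fold, 2 with the clock covariate, 3072 with limma-voom (1613 shared), 2931 with DESeq2 (1592 shared), 0 with the compared groups alone and 2843 without replicate 4 of the libraries labelled saline at 2 weeks. For the difference 1624 became 353 at 2-fold, 919 without a filter, 2459 with DESeq2 and 978 with the compared groups alone. Between the groups labelled saline 10634 became 3213 at 2-fold and 4270 with the clock covariate, and between the 100 µg groups 7568 became 1626 and 4398. The overlap of the 100 µg effects fell from 39 to 2 genes at 2-fold, and r between the doses from 0.713 to 0.222 with split saline libraries. The smaller number of controls per dose lowers that r as well.

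Leaving out 1 library gave 0 to 57 genes at 10 µg, 611 to 2085 at 100 µg and 2 weeks, 0 to 0 for dose, 0 to 3500 at 12 weeks, 777 to 2602 for the difference, 9646 to 10532 between the groups labelled saline and 6175 to 8498 between the 100 µg groups. The lists moved ran from 0 to 1 for dose and 0 to 9 between the 100 µg groups, and were 0 in the others. With the preset correlation 1, 6, 7, 9, 10, 22 and 20 lists moved at 10 µg, 100 µg and 2 weeks, dose, 12 weeks, the difference, the groups labelled saline and the 100 µg groups, and fry moved 0, 3, 1, 6, 6, 28 and 28.

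The clock covariate is built from Dbp, Per3, Arntl and Npas2, so these genes are adjusted for themselves there and their values say nothing of stability. Under it the sign changed at 100 µg and 2 weeks for Arntl (0.069), Hsp90b1 (0.064) and Npas2 (0.35), with adjusted p of 0.932, 0.959 and 0.738, for the difference for Arntl (-0.042, adjusted p = 0.898), between the groups labelled saline for Dbp (-0.32), Cx3cl1 (-0.12) and Npas2 (0.12), with adjusted p of 0.3, 0.834 and 0.84, and between the 100 µg groups for Dbp (-0.65, adjusted p = 0.000576). Without replicate 4 of the libraries labelled saline at 2 weeks, mt-Nd5, at -0.26 and not called with all libraries (adjusted p = 0.629), reversed to 0.73 between the groups labelled saline (adjusted p = 0.0407), and over all libraries left out it ran from -0.56 to 0.73.

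Replicate numbers did not pair the samples: no comparison had every same-numbered pair above a correlation of 0.1. With the replicate number as a block, 7 genes were called at 10 µg (4 shared), 1133 at 100 µg and 2 weeks, 0 for dose, 1221 at 12 weeks, 1255 for the difference, 10278 between the groups labelled saline and 7123 between the 100 µg groups. Of the 5 libraries of the first-named group, 3, 1, 1, 1, 0 and 0 correlated best with their own number at 10 µg, 100 µg and 2 weeks, dose, 12 weeks, and between the groups labelled saline and the 100 µg groups. At 10 µg the same-numbered pairs had correlations of -0.031 to 0.089. Depth limits low genes most in the library with 7.23 M counts.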

Other observations

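The list tests below were planned, except those between the 100 µg groups, which were chosen after the results were seen. Alveolar type 2 cell markers rose in 5 and fell in 2 of 10 between the groups labelled saline, 12 against 2 weeks (5 and 2 adjusted over the list alone, adjusted p = 0.789 with an estimated correlation), and rose in 5 of 10 between the 100 µg groups (5 rose and 2 fell adjusted over the list alone, adjusted p = 0.513). Natural killer cell markers fell in 3 of 8 between the groups labelled saline (1 adjusted over the list alone, adjusted p = 0.789) and in 2 of 8 between the 100 µg groups (2 adjusted over the list alone, adjusted p = 0.721). Mast cell and basophil markers rose in 2 and fell in 4 of 10 between the groups labelled saline, and rose in 2 and fell in 2 between the 100 µg groups, with the same counts adjusted over the list alone and adjusted p of 0.796 and 0.612 with an estimated correlation. Alveolar macrophage markers rose in 2 and fell in 4 of 10 between the groups labelled saline, Ear1 at -2.35, where 5 rose between the 100 µg groups (6 adjusted over the list alone), with adjusted p of 0.789 and 0.421 with an estimated correlation. Cardiac muscle genes fell in 4 of 9 and adipose genes in 3 of 6 between the 100 µg groups, with adjusted p of 0.497 and 0.572 with an estimated correlation.

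Interferon response genes rose in 1 of 13 at 100 µg and 12 weeks against the libraries labelled saline (3 adjusted over the list alone, adjusted p = 0.635 with an estimated correlation), with a median log2 fold change of 0.36. Replicate 2 at 100 µg carried this, with a score (mean log2 CPM of the list relative to the libraries labelled saline at 2 weeks) of 1.15 against -0.01 to 0.19 in the other 4 and -0.10 to 0.27 in the libraries labelled saline. Without it 0 rose, also adjusted over the list alone, and the median was 0.01. Thymus and immature T cell genes rose in 1 of 4 in the same comparison (3 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation), with a median of 0.95. The same replicate, which also held the most haemoglobin counts, had a score of 1.71 against -0.63 to 0.42 in the other 4 and -0.50 to -0.01 in the libraries labelled saline, and without it 0 rose (1 adjusted over the list alone) with a median of 0.41.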
